A study of Mus musculus with 2 samples.

How the data were processed

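The 2 libraries of ulcerated mouse skin were 1 from a sample labelled wild type and 1 from a sample labelled with whole-body Has2 overexpression. Per the labels' protocols, tissue was dissociated with dispase, accutase and collagenase, filtered, and captured with the 10x Genomics GEM-X 5' kit. The labels call the molecule total RNA for the wild-type sample and polyA RNA for the other, although the protocol text is the same for both. The treatment label begins in the middle of a sentence, so a step before tape stripping may be missing from it. The descriptions number the samples as replicates 1 and 2, but the genotypes differ, so each genotype has 1 library.

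The deposited files hold raw UMI counts per gene and cell barcode, which the authors made with Cell Ranger 9.0.1 on genome build GRCm39, per the submitters' processing notes and the file headers. The matrices are the filtered ones, which keep barcodes that Cell Ranger called as cells, per the file names. The values were whole numbers of at least 1, and both files listed the same 33696 genes with paired identifiers and symbols. The reference at hand was of build GRCm38, so no coordinates are given. No annotation of cells was used here.

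Cells with at least 200 genes and at most 15% mitochondrial UMIs were kept. These limits removed 137 and 29 wild-type barcodes and 150 and 60 others. Scrublet, run per library with an expected rate of 0.4% per 1000 barcodes, marked 0% of barcodes at its automatic threshold. As fixed beforehand for a caller that marks under 0.5%, the expected share with the highest scores was removed, 1147 wild-type barcodes and 846 others. This left 15691 and 13570 cells, with median depths of 4168 and 4157 UMIs.

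Counts were scaled to 10000 per cell and log-transformed, and 3000 variable genes were chosen across both libraries. Has2, sex-linked genes, mitochondrial genes and genes with symbols beginning with Ig, Tra or Trb were left out of the clustering. Trac, Trbc1, Trbc2 and some insulin-like growth factor and binding protein genes were kept. The rule by symbol also left out genes that are not receptor or immunoglobulin genes, and gamma-delta receptor genes were not left out. On 30 principal components and 15 neighbours, Leiden clustering at resolution 1.0 gave 30 clusters, with both libraries together and no integration. Clusters were named from 28 marker sets. A marker counted when its CPM was at least 2 times that of the median cluster, with 10 CPM added to both, and at least 10% of the cluster's cells had a UMI of it. A name needed 3 such markers, and a cluster with a median depth under 1/3 of its libraries' medians also needed a marker of its class among its top 10 genes. The markers were fixed before the data were examined, as were the gene lists, the rule for named genes, the measures and 29 alternatives. The thresholds for counting a marker, and the merging of mast cells with basophils, were set after the clusters had been seen. All names mean cells like the named type.

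UMIs were summed per library and class and scaled to CPM of the class, with exact Poisson intervals. Ratios are the library labelled Has2-transgenic over wild-type, with exact conditional (Clopper-Pearson) intervals, and shares of cells have exact binomial intervals. For a share of 0, the limit given is that of 3 counts in the total. All cover counting error only. With 1 library per genotype there was no residual spread, so no test, p-value, standard error or count of changed genes is given. Expression was compared in the 6 classes with at least 100 kept cells in each library. Each of 32 gene lists was assigned to classes beforehand. Of a list, members with at least 20 UMIs over both libraries were measured. The text gives how many were higher, the median log2 ratio with 0.5 count added, and the percentile of that median among 10000 random lists of the same size matched on mean expression. That percentile is a description of these libraries and not a test of the genotypes.

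Named genes were Has2, 2 to 4 members of each list with the largest ratios among those with at least 100 UMIs, members needed to describe a list, and in each class the 4 genes with the largest ratio in each direction. The last group needed at least 100 UMIs, at least 100 CPM in the higher library, and at least 20% of the gene's highest CPM in any class of that library. Mitochondrial, ribosomal protein, sex-linked, receptor segment, immunoglobulin, haemoglobin and unnamed gene models were left out. For each class 1 list was taken as its main result after the list values had been seen.

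Shares of cells with a Has2 UMI were compared after thinning each cell to 1000 UMIs, which left out 1061 wild-type cells and 718 others. The code for the intervals and list percentiles was checked on simulated counts. These were independent Poisson counts, the model that the intervals assume, so the check cannot show their validity in the data. There 1 cell can hold most UMIs of a gene, and genes of a list can move together. With 200 of 16508 genes changed 2-fold in counts drawn from the fibroblast class, the intervals covered 95.8% of unchanged ratios, a 2-fold list had a median of 0.99, and 39 of 40 unchanged lists lay inside the random range. In counts drawn from the T cell class with 8150 genes the values were 96.4%, 1.02 and 40 of 40. Alternatives changed the limits on cells, doublet removal, clustering, scaling (median of ratios, or TMM in edgeR 4.0.16), the count added, the UMI minimum, the weighting of cells and depth; 4 more were added after seeing the data. Random lists were drawn anew under each alternative. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.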

Results

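Single-cell gene expression was measured in ulcerated skin lesions of mice, a model of ulcerative dermatitis in which repeated tape stripping stands for scratching. The design held 2 libraries. One came from a wild-type mouse sample and the other from a sample labelled as overexpressing Has2, an enzyme that synthesises hyaluronan, in the whole body. Both were labelled with 15 days of stripping, 40 to 50 strips per day. The wild-type library held 16999 barcodes and 143875454 UMIs, with a median of 4287 UMIs and 1355 genes per barcode. In the other library there were 14622 barcodes and 134917708 UMIs, with medians of 4320 UMIs and 1571.5 genes. After filtering, 15691 and 13570 cells were kept. With 1 library per genotype no difference had a replicate check or a test, so genotype, animal and library preparation cannot be separated. All intervals are 95% intervals for counting error only, and each comparison is between these libraries.

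The first question was whether Has2 (ENSMUSG00000022367) was higher in the library labelled Has2-transgenic. Over all kept cells it was at 72.3 CPM (70.9 to 73.8) in the wild-type library and 85.8 CPM (84.2 to 87.5) in the other, a ratio of 1.19 (1.15 to 1.22). In fibroblast-like cells, which held most Has2 UMIs, the level ran the other way, 187 CPM in the wild-type library and 146 CPM in the other, a ratio of 0.781 (0.758 to 0.805). Keratinocyte-like cells had 172 and 336 CPM, a ratio of 1.95 (1.53 to 2.53), from 21 wild-type and 180 other cells. Endothelial-like cells had 2.81 and 9.17 CPM, a ratio of 3.26 (1.72 to 6.52), but 1 cell held 43.2% of the UMIs in the library labelled Has2-transgenic and the level without it was 5.23 CPM. Schwann-like cells, 71 in each library, had 37.4 and 101 CPM from 14 and 62 UMIs, a ratio of 2.70 (1.496 to 5.23), although 1 wild-type cell held 42.9% of the UMIs and the wild-type level without it was 22.7 CPM. Pericyte-like cells showed no detectable difference, with 119 and 115 CPM and a ratio of 0.967 (0.784 to 1.20). Over all kept cells but the keratinocyte-like ones the ratio was 1.06 (1.03 to 1.09), so most of the higher level over all cells came from keratinocyte-like cells, which were more frequent in the library labelled Has2-transgenic. The check of the label was therefore mixed: the gene was lower in the class that held most of its UMIs and higher, from fewer UMIs, in keratinocyte-, Schwann- and endothelial-like cells and in the leukocytes described next. The labels do not give the sequence of the transgene, and reads from the 5' end of a transgene with foreign leader sequence need not map to Has2. For these reasons the sample is called the library labelled Has2-transgenic throughout, and every direction below is a direction between these libraries.

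Has2 counts in leukocytes were low. Macrophage- or monocyte-like cells had 10 and 70 Has2 UMIs, or 0.224 and 1.85 CPM, a ratio of 8.24 (4.23 to 17.9). Neutrophil-like cells had 9 and 44 UMIs, or 0.435 and 3.75 CPM, a ratio of 8.61 (4.15 to 20.1). With every cell thinned to 1000 UMIs, 0 of 5081 wild-type macrophage- or monocyte-like cells held a Has2 UMI, which allows up to 0.0590%, against 0.111% of 4516 cells in the other library. In neutrophil-like cells the thinned shares were 0.0643% and 0.235%. Without thinning the shares in macrophage- or monocyte-like cells were 0.171% and 0.899%. T cell-like cells had thinned shares of 0.353% and 0% (0 of 159 cells, which allows up to 1.89%). Their median depths were 3794 and 3139.5 UMIs, against 8139 and 7070.5 in the macrophage- or monocyte-like cells. The T cell-like cells were too few to set a background below the other leukocyte shares, and under a whole-body label they need not lack the gene. In fibroblast-like cells the thinned shares were 13.1% and 12.2%, and the unthinned shares of 43.5% and 61.3% went with median depths of 13835 and 24532 UMIs.

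**Figure D1:**
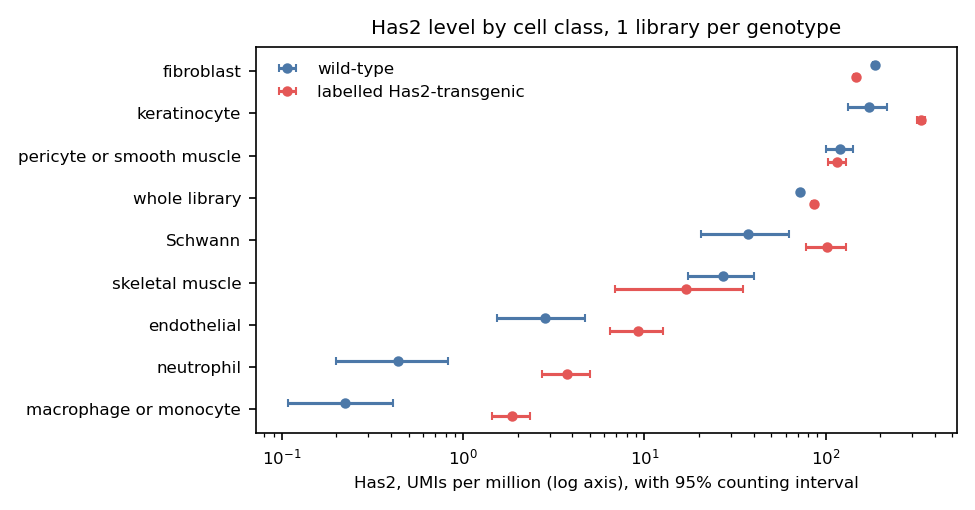
Has2 level in CPM (log axis) by cell class in the wild-type library and the library labelled Has2-transgenic; points are summed counts and bars 95% counting intervals. Has2 was highest in fibroblast-, keratinocyte- and pericyte-like cells of both libraries, lower in fibroblast-like cells of the library labelled Has2-transgenic (146 against 187 CPM) and higher in its keratinocyte-like cells (336 against 172 CPM).

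The next comparison was of cell composition. Neutrophil-like cells made up 41.1% of the wild-type library and 40.2% of the library labelled Has2-transgenic, and macrophage- or monocyte-like cells 33.6% and 34.4%. Their ratios of 0.978 (0.943 to 1.01) and 1.03 (0.986 to 1.07) showed no difference detectable at this depth. Dendritic cell-like cells were fewer in the library labelled Has2-transgenic, at 1.20% against 2.68%, a ratio of 0.448 (0.371 to 0.538). T cell-like cells were fewer too, at 1.22% against 1.84%, a ratio of 0.664 (0.545 to 0.807). Keratinocyte-like cells were more frequent at 1.33% against 0.134%, a ratio of 9.91 (6.29 to 16.4), and pericyte- or smooth muscle-like cells at 1.21% against 0.491%, a ratio of 2.46 (1.87 to 3.27).

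Fibroblast-like cells made up 16.1% and 17.2%, a ratio of 1.07 (1.01 to 1.13). One of their clusters, number 14, had a median of 994 UMIs and held 1013 wild-type cells and 268 others; without it the shares were 9.60% and 15.2%, a ratio of 1.58. Endothelial-like cells made up 2.02% and 1.92%, a ratio of 0.948 (0.802 to 1.12) that became 1.19 with at least 500 genes per cell. When each library was clustered alone, no cluster of the library labelled Has2-transgenic was named dendritic cell-like, against 0.714% of wild-type cells. This came from the naming: of the 163 dendritic cell-like cells of that library and the 421 of the wild-type library, 162 and 309 then lay in clusters named after monocytes or macrophages. Schwann-like cells made up 0.452% and 0.523%, mast cell- or basophil-like cells 0.287% and 0.287%, and plasmacytoid dendritic cell-like cells 0.198% and 0.103%. A skeletal muscle-like cluster, at 0.656% and 0.391%, did not pass the marker check for comparison. A cluster of 77 wild-type cells and no others stayed unnamed. The names were rebuilt here from markers, and shares also depend on how each tissue dissociated.

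**Figure D2:**
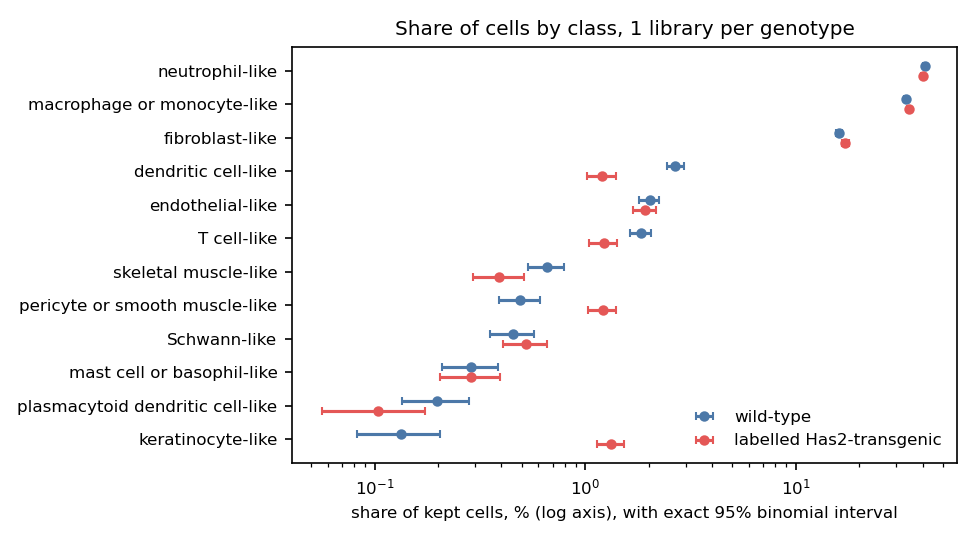
Share of kept cells by class, in percent (log axis), in the wild-type library and the library labelled Has2-transgenic, with exact 95% binomial intervals. Neutrophil- and macrophage- or monocyte-like shares lay close together, dendritic cell-like cells were at 2.68% and 1.20%, and keratinocyte-like cells at 0.134% and 1.33%.

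Expression within each class was compared to ask which gene programmes of inflammation and repair differed between the lesions. In fibroblast-like cells, genes of the extracellular matrix and of myofibroblasts were higher in the library labelled Has2-transgenic, and secreted inflammatory mediators were lower. Of the 19 measured collagen and matrix genes, 18 were higher, with a median log2 ratio of 1.39, at percentile 100 among 10000 random lists matched on expression. Col1a1 (ENSMUSG00000001506), a chain of type I collagen, was at 2793 CPM in the wild-type library and 15834 CPM in the other, a ratio of 5.67 (5.64 to 5.70). Fn1, fibronectin, had a ratio of 5.81 (5.71 to 5.92), Col1a2 of 4.64 and Col5a1 of 3.95, while Dcn, the proteoglycan decorin, was at 0.835. Of the 14 myofibroblast genes, 11 were higher, with a median of 1.97 at percentile 100. The actin-binding gene Tagln (ENSMUSG00000032085) was at 4.90 and 105 CPM, a ratio of 21.5 (18.9 to 24.7). Lrrc15 had a ratio of 14.6, Postn, which encodes the matrix protein periostin, of 9.23, and Acta2, smooth muscle actin, of 7.41, whereas Tnc and Inhba were at 0.835 and 0.781.

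Of the 17 inflammatory mediators, 16 were lower in fibroblast-like cells of the library labelled Has2-transgenic, with a median of −0.86 at percentile 0. Il6 (ENSMUSG00000025746) was at 2467 and 976 CPM, a ratio of 0.395 (0.392 to 0.399). The related cytokine Lif had a ratio of 0.220, the neutrophil growth factor Csf3 of 0.417 and Il11 of 0.426, while the monocyte chemokine Ccl2 was higher at 1.15. Of 14 cell cycle genes 13 were lower, with a median of −0.52 at percentile 0, among them the replication genes Mcm5 at 0.510 and Mcm3 at 0.520. Of 10 senescence-associated genes 7 were higher, with a median of 0.59 at percentile 99.9, including the cell cycle inhibitor Cdkn2b at 5.68 (3.69 to 9.12) and Igfbp5 at 2.47. That median was 0.31 as a mean of per-cell CPM and 0.41 with thinned cells, both inside the random range.

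Hyaluronan genes were mostly not apart from matched genes in this class. Of 10 synthesis genes 8 were lower, including Uap1 at 0.726, Gfpt2 at 0.729 and the synthase Has1 at 0.740. The median was −0.33 at percentile 1.32, and as a mean of per-cell CPM (−0.13) or with thinned cells (−0.27) it lay inside the range of 95% of random lists. Among 8 degradation genes 4 were higher, with a median of 0.02 at percentile 72.0, led by the hexosaminidase gene Hexa at 1.99. Of 12 genes for hyaluronan-binding proteins and receptors 5 were higher, with a median of −0.03 at percentile 59.8, and Tnfaip6, which remodels hyaluronan, was at 0.707. Matrix proteases split, 7 of 15 being higher with a median of −0.08 at percentile 58.7, with Mmp9 at 5.44 and Mmp11 at 4.25. Interferon response genes (8 of 20 higher, median −0.16, percentile 23.2), hypoxia and glycolysis genes (5 of 14, −0.12, 45.4) and oxidative stress genes (2 of 12, −0.26, 5.50) lay inside the range of random lists. Single members of these lists were apart, with Isg15 at 0.580, Vegfa, a growth factor for vessels, at 0.502 and the metallothionein gene Mt1 at 0.611.

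By the rule for single genes, those highest in fibroblast-like cells of the library labelled Has2-transgenic were C1qtnf3 at 37.9 (32.6 to 44.3), Reg3g at 32.2, Col7a1, which anchors epidermis to dermis, at 29.6, and Tnn at 18.9. In the wild-type library 1 cell held 77.4% of the Reg3g UMIs, and the level without it was 0.778 in place of 3.45 CPM. The lowest were Lif, the chemokines Cxcl13 at 0.336 and Cxcl14 at 0.367, and Cadm2 at 0.365. Different clusters held most of this class: numbers 14, 0 and 18 with 1013, 781 and 654 of the wild-type cells, and numbers 22 and 19 with 919 and 708 of the others. A cluster that is mostly of 1 library may be that library rather than a cell type. Beside these values, summed fibroblast markers in the class, Col1a1 and Col1a2 among them, had a ratio of 2.63 and pericyte markers of 2.08. Macrophage markers had a ratio of 2.17, but monocyte markers of 0.585 and neutrophil markers of 0.437. Suprabasal keratinocyte markers had a ratio of 2.78, from 111 and 308 CPM. Basal ones, at 4.79 and 6.59 CPM, had 1.38 and wound-edge ones 1.09, so the suprabasal ratio does not show RNA from keratinocytes. Genes of tissue dissociation and immediate early response, which move with handling, were also higher (11 of 14, median 0.43, percentile 100).

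**Figure D3:**
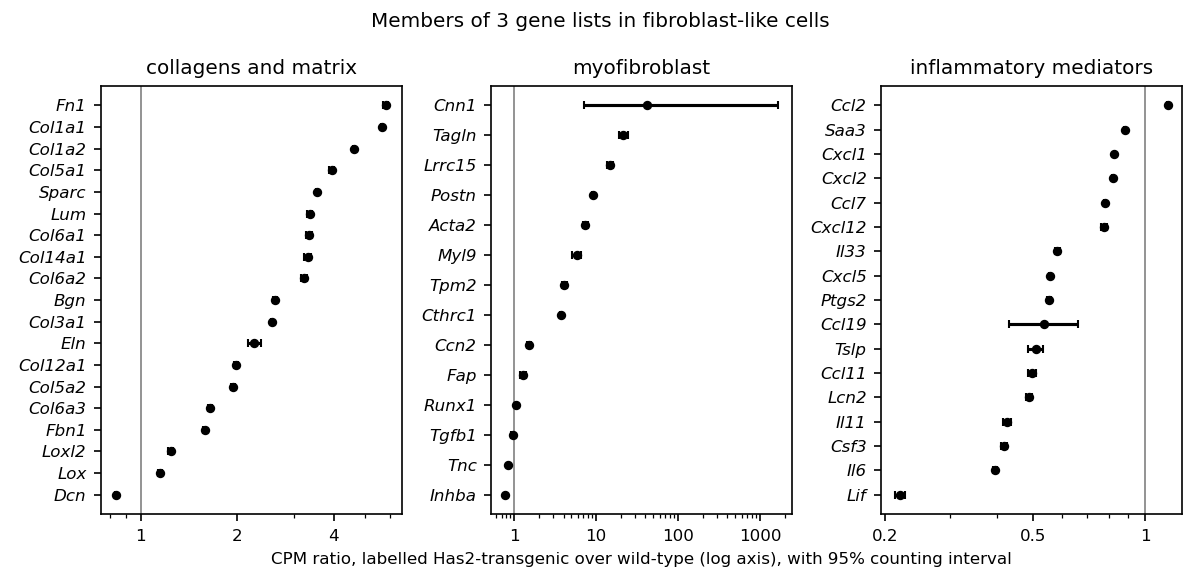
Ratio of CPM in fibroblast-like cells, library labelled Has2-transgenic over wild-type (log axes), for each measured member of the lists of collagens and matrix, myofibroblast genes and inflammatory mediators; points are ratios and bars 95% counting intervals, and the vertical line marks equal levels. Of the members, 18 of 19, 11 of 14 and 1 of 17 lie above equal levels; the Cnn1 ratio rests on wild-type UMIs from 1 cell.

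Macrophage- or monocyte-like cells of the library labelled Has2-transgenic had higher levels of antigen presentation, cell cycle and oxidative stress genes, and lower levels of inflammatory monocyte and interferon response genes. Of 10 genes of MHC class II presentation 8 were higher, with a median of 0.81 at percentile 100. H2-Aa (ENSMUSG00000036594), an MHC class II chain, was at 397 and 1028 CPM, a ratio of 2.59 (2.54 to 2.63). H2-Eb1 had a ratio of 2.59 and H2-Ab1 of 2.22, while the costimulatory gene Cd80 was at 0.476. All 14 cell cycle genes were higher, with a median of 1.26 at percentile 100. Their levels were low, as in Ube2c with 4.12 and 18.7 CPM, a ratio of 4.53 (3.85 to 5.36), and Cdk1 with 2.42 and 10.2 CPM, a ratio of 4.22, from 44 and 108 cells. Cluster 28, with Top2a and Ube2c among its leading genes, held 19 wild-type cells and 54 others and 16.0% and 38.9% of the cell cycle UMIs of the class. Its median depth was 24891 UMIs, against 8139 and 7070.5 for the class in the 2 libraries. Without this cluster, an alternative chosen after seeing the data, the cell cycle median was 0.62 at percentile 99.5. Of 12 oxidative stress genes 9 were higher, with a median of 0.46 at percentile 100, among them the glutathione synthesis genes Gclc at 1.55 and Gclm at 1.47.

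Of 12 genes of inflammatory monocytes 9 were lower, with a median of −0.77 at percentile 0. They included S100a8 at 0.377 (0.366 to 0.388), S100a9 at 0.445 and the chemokine receptor Ccr2 at 0.409, while Ly6i was at 2.35. S100a8 and S100a9 were also neutrophil markers here, and RNA from neutrophils was not tested for this list. Of 20 interferon response genes 17 were lower, with a median of −0.30 at percentile 0, including Ifit1 at 0.413 and Gbp2 at 0.519. Hyaluronan-binding and receptor genes were lower in 7 of 10 cases, with a median of −0.46 at percentile 0. The innate receptor Tlr4, a reported sensor of hyaluronan fragments, was at 0.467 (0.450 to 0.485) and the proteoglycan Vcan at 0.526, while Hmmr, which also serves in mitosis, was at 4.08 from 1.05 CPM. The hyaluronan degradation list (6 of 8 higher, median 0.13, percentile 81.5) and the interleukin-1, TNF and NF-kB list (3 of 17, −0.18, 4.58) lay inside the random range, with Hexa at 1.36, Ccl2 at 0.418, Cxcl3 at 0.547 and Tnf at 1.58. So did reparative macrophage genes (10 of 17, 0.09, 82.4), which split between the growth factor Igf1 at 2.32 and the chemokine Ccl8 at 2.25 and Arg1, arginase, at 0.453. Matrix proteases (7 of 14, −0.13, 8.40) and hypoxia and glycolysis genes (9 of 14, 0.07, 81.0) were inside it as well, although Mmp9 was at 17.4 and its inhibitor Timp1 at 0.453, and Hif1a was at 0.580.

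The single genes highest in this class were Ctsk (ENSMUSG00000028111), the protease cathepsin K, at 27.8 and 718 CPM, a ratio of 25.9 (24.4 to 27.4), then Mmp9, Acp5, a phosphatase of osteoclasts and macrophages, at 7.44, and the stress-induced cytokine Gdf15 at 6.20. One wild-type cell held 32.8% of the Ctsk UMIs, and without it the wild-type level was 18.7 CPM. The lowest were Ppbp at 0.241, AA467197 at 0.291, the chemokine Ccl24 at 0.320 and Ccr2. Clusters 2, 3 and 1 held 1788, 1428 and 953 of the wild-type cells, and clusters 4, 9 and 3 held 1505, 984 and 818 of the others. Summed macrophage markers in the class had a ratio of 2.03 and monocyte markers of 0.625. Neutrophil markers had a ratio of 0.746, from 947 and 707 CPM. That set includes Mmp9, which was at 17.7 and 308 CPM, so the other neutrophil markers together fell further than this ratio shows. Handling genes were higher here too (13 of 14, median 0.53, percentile 100).

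In neutrophil-like cells, oxidative stress and NF-kB target genes were higher in the library labelled Has2-transgenic, and interferon response genes were lower. Of 12 oxidative stress genes 11 were higher, with a median of 0.55 at percentile 100. They included Txnrd1, thioredoxin reductase, at 2.20 (2.12 to 2.28) and the haem oxygenase gene Hmox1 at 1.76. Of 17 interleukin-1, TNF and NF-kB genes 15 were higher, with a median of 0.49 at percentile 99.97, among them the chemokine Ccl3 at 2.06, the NF-kB inhibitor Nfkbia at 2.06 and Ptgs2, cyclooxygenase 2, at 1.76. This median was 0.29 without doublet removal, inside the random range that reached 0.30. Of 17 interferon response genes 12 were lower, with a median of −0.39 at percentile 0.230, including Zbp1 at 0.535 and Oas1a at 0.636.

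Neutrophil activation genes went both ways (8 of 15 higher, median 0.04, percentile 46.4). The granule genes Mmp8 and Ngp were at 0.298 and 0.280 and Retnlg at 0.306 (0.304 to 0.309), with 19709 and 6034 CPM, whereas Camp was at 4.52 with 71.2% of its UMIs in 1 cell, and without that cell at 6.56 CPM against 5.03 CPM in the wild-type library. Matrix proteases (8 of 13 higher, 0.19, 77.3) and hypoxia and glycolysis genes (9 of 14, 0.12, 86.0) lay inside the random range, with the gelatinase gene Mmp9 at 0.467 and Ndrg1 at 1.65. The single genes highest in this class were Plau (ENSMUSG00000021822), the plasminogen activator urokinase, at 3.61 (3.31 to 3.95), Rasip1 at 3.12, the integrin Itgax at 2.86 and Cd300c2 at 2.66. The lowest were Ifitm6 at 0.197 (0.185 to 0.210), the neutrophil surface marker Ly6g (ENSMUSG00000022582) at 0.229, Ngp and Mmp8. In the library labelled Has2-transgenic 1 cell held 64.3% of the Ngp UMIs, and the level without it was 39.5 in place of 111 CPM. Clusters 6, 11 and 12 held 1501, 1346 and 1324 of the wild-type cells, and clusters 5, 13 and 7 held 2083, 1377 and 1084 of the others. Median depth was 3061 and 2053 UMIs. Summed neutrophil markers in the class were at 180946 and 124064 CPM, a ratio of 0.686. Fibroblast markers had a ratio of 2.81, basal keratinocyte markers of 7.12 and conventional dendritic cell markers of 2.12. The dendritic set includes Itgax, at 57.8 and 165 CPM of the set's 91.3 and 194 CPM, and its rise lay in that gene. Handling genes were higher (13 of 14, median 0.92, percentile 100).

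Endothelial-like cells of the library labelled Has2-transgenic had higher interferon response, angiogenesis and activation genes. Of 17 interferon response genes 16 were higher, with a median of 0.84 at percentile 100. The chemokine Cxcl10 (ENSMUSG00000034855) was at 17.7 and 143 CPM, a ratio of 8.09 (6.46 to 10.2), and 1 cell held 40.9% of its wild-type UMIs, without which the wild-type level was 10.5 CPM. The antiviral gene Rsad2 had a ratio of 6.59 and the signalling gene Stat2 of 2.11. Of 14 angiogenesis genes 10 were higher, with a median of 0.55 at percentile 99.99, including Esm1, a marker of tip cells, at 4.15 (39.1% of the wild-type UMIs in 1 cell, and 5.66 in place of 9.25 CPM without it) and the placental growth factor gene Pgf at 3.18, while Aplnr was at 0.504. Of 12 activation genes 10 were higher, with a median of 0.43 at percentile 99.9, among them the leukocyte adhesion genes Vcam1 at 1.90 and Sele at 1.87. Of 14 cell cycle genes 9 were lower, with a median of −0.26 at percentile 1.34. It lay inside the random range with members of at least 100 UMIs (−0.17), without doublet removal (−0.22) and with cells thinned to equal depth (0.18).

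Hyaluronan synthesis (5 of 9 higher, 0.08, 65.9), oxidative stress (5 of 12, −0.04, 38.5) and hypoxia and glycolysis genes (8 of 14, 0.09, 68.2) lay inside the random range in endothelial-like cells. Uap1 was at 1.44, the metallothionein gene Mt2 at 0.573 and Adm, adrenomedullin, at 3.45. The single genes highest in this class included 3 markers of lymphatic vessels. Ccl21a (ENSMUSG00000094686) was at 1.61 and 1210 CPM, with all 8 wild-type UMIs in 1 cell; in the other library 1 of 19 cells with the transcript held 36.6% of the UMIs, and the level without it was 778 CPM. Mmrn1 was at 35.3 (21.5 to 62.2) and Lyve1, a hyaluronan receptor, at 8.02 (6.70 to 9.68), next to Cxcl10. For Mmrn1, 1 wild-type cell held 81.3% of the UMIs, and the wild-type level without it was 0.604 in place of 3.22 CPM. Cells with UMIs of at least 3 of the 6 lymphatic markers were 5 of 317 wild-type cells, or 1.58% (0.514 to 3.64), and 23 of 260 others, or 8.85% (5.69 to 12.98). These shares were not thinned, and the median depths of the class were 8490 and 12008.5 UMIs. Without the lymphatic-marked cells the interferon response median was 0.93 and the angiogenesis median 0.60. The lowest genes were Igfbp3 at 0.464, Ctla2b at 0.493, Aplnr and the splicing factor gene Srsf1 at 0.508. Summed fibroblast markers in the class had a ratio of 4.20 and pericyte markers of 2.35, and melanocyte markers were at 0.201 and 79.5 CPM. Handling genes were higher (13 of 14, median 0.88, percentile 100).

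T cell-like cells numbered 289 and 166, all of cluster 8, which was named from gamma-delta T cell markers. At resolution 2.0 they fell into a gamma-delta cluster of 141 and 48 cells and an alpha-beta cluster of 148 and 118. The values of this class thus also reflect its mix of T cells. Regulatory T cell genes were higher in the library labelled Has2-transgenic in 8 of 9 cases, with a median of 0.91 at percentile 100. Foxp3 (ENSMUSG00000039521), the defining transcription factor of regulatory T cells, was at 83.7 and 352 CPM, a ratio of 4.21 (3.31 to 5.38). The costimulatory receptor Tnfrsf4 had a ratio of 7.31 (5.81 to 9.27), and the inhibitory receptors Ctla4 and Tigit had 2.94 and 2.63. The median was 0.54 with cells thinned to equal depth. Genes of type 17 lymphocytes (5 of 9 higher, 0.10, 82.5), cytotoxic effectors (4 of 9, −0.17, 16.9) and type 2 responses (3 of 7, −0.05, 40.5) lay inside the random range, with the interleukin-23 receptor gene Il23r at 0.510, the granzyme gene Gzma at 0.338 and Il1rl1, the receptor of interleukin-33, at 2.65. Interferon response (7 of 12, 0.17, 91.0), hypoxia and glycolysis (4 of 11, −0.15, 16.6), oxidative stress (2 of 11, −0.22, 6.99) and cell cycle genes (4 of 8, −0.06, 53.1) were inside it as well, with Bst2 at 1.60, Ndrg1 at 1.504, Hmox1 at 0.569 (1 cell in each library held 42.9% and 37.1% of its UMIs, and the levels without these were 119 and 74.7 CPM) and Top2a at 1.47 (0.995 to 2.14).

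Single genes highest in T cell-like cells were Il17f at 36.0, Klrg1 at 9.32 (6.43 to 13.9), the decoy receptor Il1r2 at 7.55 and Tnfrsf4. Of the Il17f UMIs in the library labelled Has2-transgenic, 95.2% came from 1 cell, and the level without it was 16.9 in place of 351 CPM, against 9.75 CPM in the wild-type library. For Il1r2, 1 cell in each library held 37.3% and 35.5% of the UMIs, and the levels without these were 34.5 and 272 CPM. Among the lowest were Dhx40 at 0.334, Gzma and Trpm6 at 0.418. Among T cell markers, singled out after their values were seen, Cd4 was at 2.33 (1.67 to 3.26), the gamma-delta receptor gene Trdc at 0.396 (0.327 to 0.477) and Trbc1 at 0.389. The other gamma-delta markers Trdv4, Trgv2 and Blk were at 1.03 (0.916 to 1.16), 1.05 (0.630 to 1.72) and 0.692, and Trac and Trbc2 at 1.24 and 0.862. Summed gamma-delta markers had a ratio of 0.740 (0.679 to 0.807) and alpha-beta markers of 1.03. Summed neutrophil markers in the class had a ratio of 0.125, macrophage markers of 2.19 and fibroblast markers of 0.359. Handling genes were higher (11 of 14, median 0.70, percentile 100), with a median of 0.24, inside the random range, in thinned cells.

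Dendritic cell-like cells numbered 421 and 163, all of cluster 16, which was named from 5 of 6 markers of migratory dendritic cells but had 1 marker of its class and 1 of natural killer cells among its 10 leading genes. With each library clustered alone, 112 of these wild-type cells and 0 of the others lay in a cluster named dendritic cell-like. Summed markers of migratory dendritic cells had a ratio of 0.810 (0.778 to 0.843) and those of conventional ones 1.07, so the values of this class also reflect which cells the cluster held. Of 10 genes of MHC class II presentation 8 were higher in the library labelled Has2-transgenic, with a median of 0.29 at percentile 99.9. The invariant chain gene Cd74 (ENSMUSG00000024610) was at 20996 and 29557 CPM, a ratio of 1.41 (1.39 to 1.42), and H2-Ab1 had a ratio of 1.34, while Cd80 and the transactivator Ciita were at 0.614 and 0.682. The single genes highest in the class were Acss2 at 5.53, Lyz2, lysozyme of myeloid cells, at 4.86 (4.56 to 5.19), the haem-degrading enzyme genes Hmox1 at 4.83 and Blvrb at 3.83. For Acss2, 1 cell in each library held 30.5% and 27.9% of the UMIs. Lowest were the chemokine Ccl17 (ENSMUSG00000031780) at 0.161 (0.128 to 0.2004), which attracts T cells, Ccnd2 at 0.256, AA467197 at 0.292 and Glipr2 at 0.381. Summed macrophage markers in the class had a ratio of 1.59 and fibroblast markers of 2.75.

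**Figure D4:**
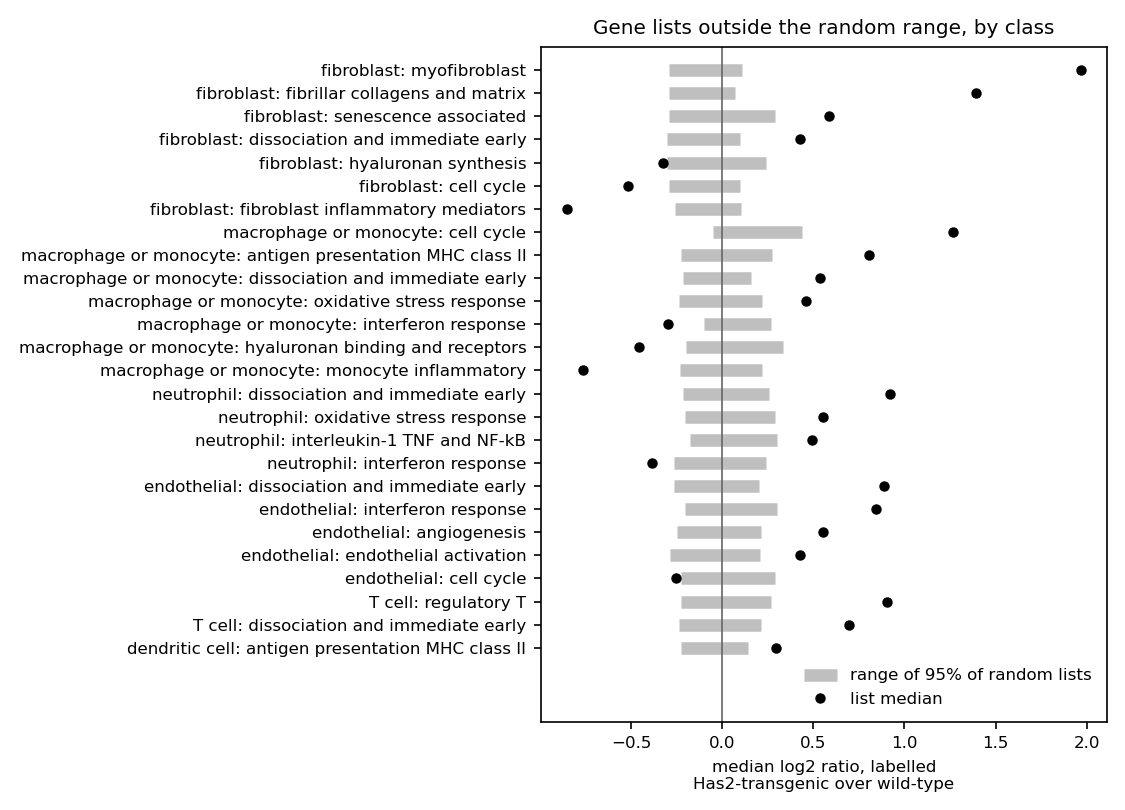
Median log2 ratio, library labelled Has2-transgenic over wild-type, of the gene lists whose median lay outside the range of 95% of random lists in the 6 classes compared; dots are list medians and grey bars that range. The myofibroblast list in fibroblast-like cells lies at 1.97 and the cell cycle list in macrophage- or monocyte-like cells at 1.26, while the inflammatory mediator list in fibroblast-like cells lies at −0.86.

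Summed over all kept cells, the lists also reflect the shares of cells and their depths. Handling genes were higher in the library labelled Has2-transgenic (12 of 14, median 0.61, percentile 100). Cell cycle genes (10 of 14, 0.35, 99.8) and oxidative stress genes (8 of 13, 0.26, 99.5) were higher too, although the first median, 0.33 in thinned cells, then lay inside the random range. Type 2 and itch genes were lower in 10 of 15 cases, with a median of −0.39 at percentile 0.0700; the chemokine genes Ccl17 and Ccl22 were at 0.0874 and 0.185, and the median was −0.01, inside the random range, with no minimum of UMIs. Interferon response genes were lower in 15 of 20 cases, with a median of −0.27 at percentile 0.160 that became −0.17, inside the random range, without doublet removal. Genes of the interleukin-1, TNF and NF-kB list were lower in 14 of 17 cases (median −0.28, percentile 0.380), but the median was 0.11 as a mean of per-cell CPM and 0.08 with thinned cells, both inside the random range. All 10 MHC class II presentation genes were lower, with a median of −0.29 at percentile 0.640 that became 0.23, above the random range, and 0.22, inside it, under the same changes. Hyaluronan synthesis (5 of 10 higher, −0.01, 63.6), degradation (7 of 8, 0.12, 86.6) and binding genes (6 of 14, −0.06, 23.9) lay inside the random range, with the synthase Has3 at 2.497 from 0.331 CPM. Angiogenesis (7 of 14, 0.05, 68.3), hypoxia and glycolysis (7 of 14, −0.01, 67.4) and haemoglobin genes (1 of 4, −0.29, 3.99) did so as well. The female-specific transcript Xist was at 251 and 237 CPM, and the Y-linked genes had at most 4 UMIs in either library, so neither library was apart from the other by sex.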

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

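No paired analysis was possible because each genotype has 1 library. Of the alternatives, 4 were chosen after seeing the data. They left out the fibroblast-like cluster of low UMI count, from the shares and from the lists, lymphatic-marked endothelial-like cells, and macrophage-like cluster 28, with cell cycle genes among its 10 leading genes. The rest were planned. Of 64 alternative shares, 57 stayed inside the counting interval of the reported ratio. With at least 500 genes per cell the ratio was 0.917 for neutrophil-like, 1.21 for fibroblast-like and 1.19 for endothelial-like cells. Without the low-UMI cluster it was 1.58 for fibroblast-like cells. Dendritic cell-like cells had 0.575 at resolution 0.5 and 0 with the libraries clustered separately, where naming put 160 of the 163 such cells into a cluster named after monocytes. Pericyte-like cells then had 3.47. The share that leaves out keratinocytes cannot give a keratinocyte ratio. The fibroblast Has2 ratio was 0.823 with median-of-ratios scaling, 0.809 without doublet removal and 0.900 as a mean of per-cell CPM, all below 1; the other 4 of 7 Has2 values stayed inside their intervals.

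Of 726 alternative list medians, 620 stayed inside the spread of the main one, 101 moved and 5 were counted as taking the other sign. A change of sign was counted only for the 33 of 63 list and class pairs whose main median lay outside the random range. These pairs had 382 alternative values. Sign changes in the other pairs are among the values that moved or stayed. The fibroblast matrix median was 1.47 with median-of-ratios scaling, 1.44 with TMM, 1.65 as a mean of per-cell CPM, 1.62 with thinned cells and 1.36 without the low-UMI cluster. With thinned cells the macrophage MHC class II median was 1.06, the regulatory T median 0.54 and the neutrophil interleukin-1 and TNF median 0.36. In unthinned cells the macrophage MHC class II median was 0.95 with cluster 28 left out. The neutrophil interleukin-1 and TNF median was 0.29 in unthinned cells without doublet removal. Over the whole library the interleukin-1 and TNF median took the other sign as a mean of per-cell CPM (0.11) and with thinned cells (0.083), as did the MHC class II median (0.23 and 0.22). Both settings weigh deep cells less. The endothelial cell cycle median was 0.18 with thinned cells, −0.17 with members of at least 100 UMIs and −0.22 without doublet removal, each inside the random range.

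Of 1398 alternative values of 233 gene and class pairs, 886 stayed inside the counting interval and 495 moved. A change of sign was counted only where the main interval left out equal levels, and 17 such values in 14 pairs took the other sign. With thinned cells these log2 ratios were −0.59 for Apln, 1.77 for Birc5, 0.84 for Ccnb2, 0.73 for Mcm3 and 0.040 for Ube2c in endothelial-like cells, and −0.074 for Gbp3, −0.11 for Gdf15, 0.99 for Hmmr and −0.11 for Ifit2 in fibroblast-like cells. As means of per-cell CPM they were −0.055 for Atf3 in T cell-like cells, 0.31 for Birc5 in endothelial-like cells, and 0.16 for Cemip2, 0.32 for Hmmr, −0.39 for Ifit2 and −0.014 for Tlr2 in fibroblast-like cells. Without doublet removal they were 0.34 for Il5 in T cell-like cells and −0.26 for Mmp14 in neutrophil-like cells. For every value that moved or took the other sign, except the dendritic share of 0, the cause was not tested. Depth limits the classes with few cells and the genes with few UMIs.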

Other observations

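Keratinocyte-like cells, 21 in the wild-type library and 180 in the library labelled Has2-transgenic, were too few for the comparison of classes, and their values are given as values only. In the library labelled Has2-transgenic the wound keratin genes Krt6b and Krt16 were at 2997 and 4904 CPM, against 30.8 and 563 CPM in the wild-type library. Of 17 wound keratinocyte genes 14 were higher, with a median log2 ratio of 1.05, while the protease inhibitor gene Slpi was at 0.152. Of 16 differentiation and barrier genes 14 were higher, with a median of 2.26. Of these, 7 had 0 wild-type UMIs, and the median was 1.63 with such genes at the bound set by 3 counts. On that bound Cdsn was at 0.713 and Klk5 at 0.891, so neither can be called higher. Krt1, a keratin of suprabasal cells, was at least 26.6-fold higher on that bound, and Krt10 was at 17.5 (7.46 to 53.9). Of 12 basal and hemidesmosome genes 10 were lower, with a median of −0.92, including the laminin gene Lama3 at 0.351 and Col17a1 at 0.365, although Krt14 was at 2.51. Among 9 alarmin genes 7 were higher, with a median of 3.002, or 2.39 at the bound; Tslp and Il33 were at least 8.25-fold and 5.23-fold higher. The type 17 epithelial list had a median of 1.91, which was −0.43 with its 5 genes of 0 wild-type UMIs at the bound, so it gives no direction.

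The other lists in keratinocyte-like cells had medians of 0.34 for the cell cycle (10 of 14 higher), 0.44 for oxidative stress (7 of 13), 0.33 for senescence (6 of 8), −0.26 for hyaluronan synthesis (4 of 10), −0.17 for hyaluronan binding (2 of 5), −0.35 for the interferon response (2 of 5) and −0.26 for hypoxia and glycolysis (6 of 14). Scaling moved all genes of this class by 0.18 (TMM) or 0.15 (median of ratios) on the log2 scale. In pericyte- or smooth muscle-like cells, 77 and 164 in number, 10 of 14 myofibroblast genes were higher, with a median of 0.65.

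Of the tests below, those of TMM scaling and of the low-UMI cluster for the matrix list, of handling in small classes and of cells with few mitochondrial UMIs and many genes were chosen only after the result was seen. Has2 UMIs in macrophage-, monocyte- and neutrophil-like cells were more frequent in the library labelled Has2-transgenic. Free RNA or doublets from fibroblasts and keratinocytes were judged by fibroblast and basal keratinocyte markers. By these markers they accounted for less than was seen, since observed over expected Has2 was 4.91 (4.05 to 5.90). A higher free RNA level in the library labelled Has2-transgenic would need the expected level to differ as the observed one did. By the same markers the ratio of the expected level was 1.02, but this sums fibroblast and keratinocyte parts. The keratinocyte marker share alone was 0.0121% in wild-type neutrophil-like cells and 0.0855% in the others. In macrophage- or monocyte-like cells it was 0.0231% and 0.0415%. Wound-edge keratinocyte markers, not in the test, had ratios of 12.6 and 8.24. Suprabasal ones were higher in neutrophil-like cells only. The test thus cannot show equal free RNA from keratinocytes, which stays open. Among leukocytes with no UMI of the fibroblast and basal keratinocyte markers the Has2 ratio was still 10.6 (5.22 to 24.3). It came from 58 UMIs in 34 of 6522 cells against 9 UMIs in 9 of 9117. This argues against capture together with a cell that carries these markers. T cell-like cells had 1.63 and 1.68 CPM from 2 UMIs and 1 UMI, too few to exclude a source that reaches all cells alike, which stays open, as do genotype and any other difference between the samples.

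Collagen and matrix genes were higher in fibroblast-like cells of the library labelled Has2-transgenic. With cells thinned to equal depth the median was 1.62, above the range of 95% of random lists drawn from the thinned counts, −0.32 to 0.08, which argues against depth as the whole cause. Counts taken by a few genes would move all genes of the class by about the list median of 1.39, but TMM scaling moved them by 0.045. The range of 95% of random lists in unthinned cells, −0.29 to 0.07, already left no room for such a shift. The TMM value is therefore no separate check. The low-UMI cluster held 3.63% of the wild-type fibroblast UMIs, where diluting the list that far would need 60.0%. RNA from other cells was not tested for this list, and with 1 library per genotype lesion stage, site, animal and genotype stay open.

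Dissociation and immediate early genes were higher in fibroblast-, macrophage- or monocyte-, neutrophil-, endothelial- and T cell-like cells and over the whole library. Among cells with at most the median mitochondrial share and at least the median gene number of their class, the lowest median in the first 4 classes was 0.35, above its random range of −0.20 to 0.15, which argues against damaged cells as the whole source there; in T cell-like cells, 69 and 38 in number, it was 0.15 inside −0.26 to 0.31, too few to decide. Handling before capture was assumed to raise the list in every class, which was not shown. The median was above 0 in 4 of 6 smaller classes. It was 0.78 in pericyte-, 0.26 in mast cell- or basophil-, 0.20 in plasmacytoid dendritic cell- and 0.02 in skeletal muscle-like cells. In Schwann- and keratinocyte-like cells it was −0.02 and −0.58. The pericyte value lay above its random range, 4 lay inside theirs, and the keratinocyte value lay below its own, which began at −0.54. By the bound first written the keratinocyte value would have excluded handling. A minimum of 50 cells per library was set after that value was seen, because it rests on 21 wild-type cells. Mast cell- or basophil-like cells (45 and 39) and plasmacytoid dendritic cell-like cells (31 and 14) fall under that minimum too. Of the classes that pass it, pericyte- and skeletal muscle-like cells lay above 0 and Schwann-like cells did not. The skeletal muscle-like cluster did not pass the marker check. Handling and genotype thus cannot be told apart, since each genotype was dissociated once.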
